A study of Mus with 17 samples.

How the data were processed

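RNA was measured in the abdominal aorta of wild-type C57BL/6 mice, a common inbred laboratory strain. Per the labels' protocols, total RNA was extracted with Trizol, ribosomal RNA was removed with a depletion kit, and libraries were made from 1 μg of RNA with a kit for Illumina sequencing. The 17 samples fell into 3 groups: saline (Control, n = 5), angiotensin II at 500 ng/kg/min (AngII, n = 6), and the same infusion with neferine at 1 mg/kg/day (AngII with neferine, n = 6), each over 42 days. Groups and replicate numbers were taken from the sample titles, in which Control has no replicate 3. The labels describe mice but do not say how many animals went into a sample, so the p-values measure the spread between these samples.

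The deposited files hold 1 column per sample, a linear abundance signal per transcript that is never negative, and per the file headers the unit is not named. The column totals, 392615 to 569873, differ between samples and are not those of a complete TPM table. Transcripts carry Ensembl identifiers or identifiers of the form MERGE, locus and isoform, which are called assembled transcripts here. The aligner, the assembler, the quantification tool, the genome build and the annotation are not given in the sources used here. The submitters' processing notes name limma without a version or a role. No replicates were pooled. An exact 0 can be a failed estimate, so such values are described as listed at 0, and no fold is given against a group at 0.

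The 11 Control and AngII files listed 43752 transcripts each and the 6 neferine files 41642, of which 39614 were shared. Each transcript of the first set had a mean of at least 0.5 in Control or in AngII. In the second set, the 1701 shared transcripts with an AngII mean under 0.5 all had a neferine mean of at least 0.5. Such a minimum does not account for 393 transcripts with an AngII mean of at least 0.5 (1.03% of those in the files) that the neferine files do not list. The neferine group and its file set cannot be told apart in any comparison that involves it, while Control and AngII belong to 1 set. The means of the shared assembled transcripts correlated between AngII and neferine with a Spearman rho of 0.736 across transcripts, against 0.705 between Control and AngII, so an identifier was taken to stand for the same transcript in both sets.

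The read depth is unknown because the files hold no counts. The relative depth was estimated from low values, in which 1 fragment of a transcript makes a step that shrinks as depth grows. The commonest ratio of values under 0.05 between a library and AngII replicate 5, within a window of 0.02 on the log2 scale, gave relative depths of 0.980 to 1.11. It rested on 24.4% to 32.5% of the 116 to 310 low values compared. No interval that needs a count was computed. No 2 libraries were duplicates, since at most 0.414% of transcripts had an equal value above 0 in any pair.

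Values were tested as log2(value + 1) with limma 3.58.1 in R 4.3.3 (a linear model per transcript with trended, robust empirical Bayes moderation), all 17 samples entering 1 fit with a term per group and no covariate. Transcripts with a value of at least 1 in at least 5 libraries were kept, which left 29983 transcripts, 21957 from Ensembl and 8026 assembled. A transcript was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are on the log2(value + 1) scale, which understates the change of low transcripts. The designs, alternatives and rules for named genes were fixed before the data were examined. The design had provided a count test for counts and limma for FPKM, TPM or similar values. The values matched neither description by name, and the limma branch was used.

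The files do not pair transcripts with gene names, and 0 transcripts matched the RefSeq gene table of assembly GRCm38.p6 used here, which lists no Ensembl identifiers. Tests were therefore made per transcript. The 56 planned gene lists, which included the markers of cell types in or next to the aorta, and the 30 planned single genes could not be tested, and no coordinates are given. The fixed rule named the 8 called genes with the largest rise and the 8 with the largest fall, with non-overlapping groups first, or, where no gene was called, the 5 with the smallest p in each direction. It required a mean of at least 1 and a gene symbol. Without symbols that condition was dropped, and at most 2 identifiers are printed in each direction for a comparison.

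The script was tested on simulated data with the means and spreads of the real transcripts, with 50 transcripts changed at each fold size among 29983. For AngII against Control it recovered 26% of changes of 1 on the log2 scale, 66% of changes of 2 and 94% of changes of 3, with 8 false calls. For neferine against AngII the shares were 18%, 60% and 90%, with 7 false calls. For neferine against Control they were 18%, 76% and 80%, with 7 false calls. Chance levels for pairs of comparisons that share libraries came from 20 simulated datasets with unchanged groups, and observed values were repeated with the shared group split. Library measures were compared with two-sided exact permutation tests. The alternatives were quantile normalization, no filter, a stricter filter, an exact rank sum test, limma without trend, a pseudocount of 0.1, fits of only the groups compared, the replicate number as a block, a minimum log2 fold change of 1, and each library left out. Plots were drawn with matplotlib 3.10.9.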

Results

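The study asked how neferine, an alkaloid of lotus seeds, acts on blood vessels of mice whose blood pressure is raised by angiotensin II, a peptide hormone that constricts vessels, and which genes differ between the 3 groups. Abundance signals per transcript were available for 5 abdominal aorta samples of mice given saline (Control), 6 of mice infused with angiotensin II (AngII) and 6 of mice given the same infusion and neferine, after 42 days. The number of reads behind the signals is unknown. Estimated depths relative to each other were similar, at 1.05 ± 0.0373 (SD, n = 5) in Control, 1.04 ± 0.0460 (SD, n = 6) in AngII and 1.06 ± 0.0399 (SD, n = 6) with neferine. Because the files do not pair transcripts with gene names, the comparisons below are of transcripts by identifier.

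Most libraries resembled each other, and 3 stood apart. AngII replicate 6 had a median Spearman rho of 0.455 with the other 16 libraries across transcripts, against 0.606 to 0.680 in those 16, and 16.4% of its shared transcripts were listed at 0. It lay at 181.6 on the first principal component, which held 15% of the variance, and the next library, neferine replicate 1, at 77.1. The 10 highest transcripts took 31.0% of the signal of AngII replicate 2 and 29.0% of that of neferine replicate 1. Those 2 libraries lay at -86.2 and -99.9 on the second component. On the third component, which held 7.88% of the variance, the Control libraries lay between -68.2 and -22.2. AngII replicate 2 and neferine replicate 1 lay within that range, at -39 and -30.8. All other AngII and neferine libraries lay above it, between -8.8 and 63.1. The separation on this component was not tested. No difference between groups was detected in the share of transcripts at 0, the share of the 10 highest or the share of assembled transcripts (9 two-sided exact permutation tests, each with a Benjamini-Hochberg adjusted p of 0.989).

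**Figure D1:**
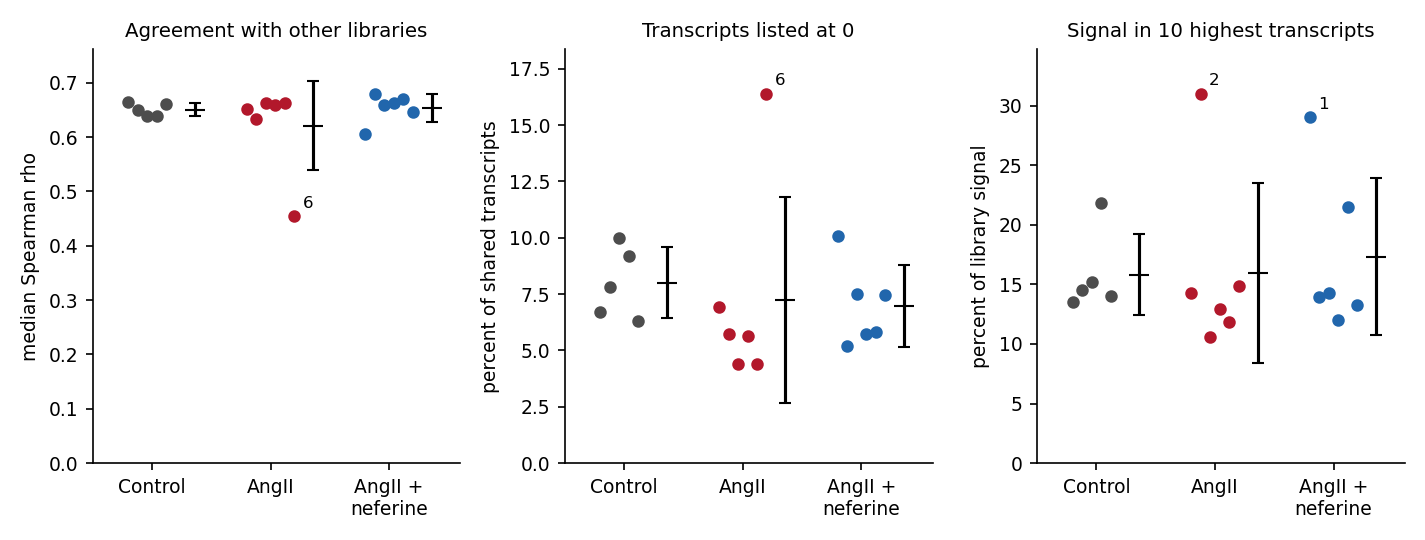
Measures of each library by group, with points for single libraries and bars for the mean ± SD (n = 5, 6 and 6); the vertical axes give the median Spearman rho with the other libraries, the percent of shared transcripts listed at 0 and the percent of signal in the 10 highest transcripts. AngII replicate 6 has the lowest rho, 0.455, and AngII replicate 2 and neferine replicate 1 have the highest shares in the 10 highest transcripts, 31.0% and 29.0%.

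**Figure D2:**
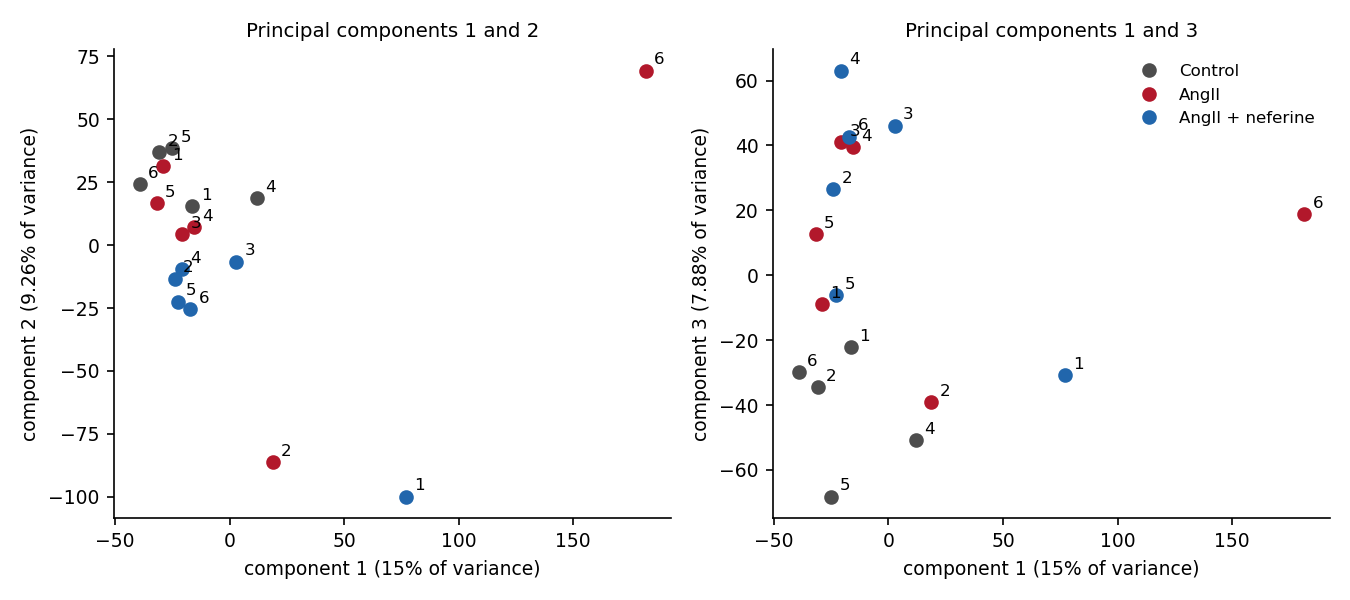
Principal components of log2(value + 1) over 29983 transcripts, with 1 point per library labelled by its replicate number; axes give the component scores and their percent of the variance. AngII replicate 6 lies at 181.6 on component 1, and AngII replicate 2 and neferine replicate 1 lie lowest on component 2. On component 3 the Control libraries lie between -68.2 and -22.2. All AngII and neferine libraries lie above them, other than AngII replicate 2 and neferine replicate 1.

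AngII was compared with Control to find transcripts that differ after angiotensin II infusion. The assembled transcript MERGE.9452.1 had the smallest p. Its value was 5.57 ± 0.944 (SD, n = 5) in Control and 18 ± 5.29 (SD, n = 6) in AngII, a log2 fold change of 1.5 ± 0.22 (SE) that did not pass (limma, adjusted p = 0.095), with every AngII library above every Control library. ENSMUST00000177974 had a value of 74.5 ± 10.1 (SD, n = 5) in Control and 25.7 ± 9.84 (SD, n = 6) in AngII, and its log2 fold change of -1.58 ± 0.26 (SE) did not pass either (limma, adjusted p = 0.122). A pair of assembled transcripts of 1 locus took each other's place. MERGE.36888.4 was listed at 0 in all 5 Control libraries and lay between 4.78 and 23.4 in AngII (limma, adjusted p = 0.122). MERGE.36888.5 lay between 11.5 and 29.6 in Control, was listed at 0 in 4 AngII libraries and was at most 0.0154 in the others (limma, adjusted p = 0.114). The summed signal of the locus was 19 ± 6.86 (SD, n = 5) in Control and 15.5 ± 6.00 (SD, n = 6) in AngII, a difference within the spread (limma over 5368 loci, adjusted p = 0.878).

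Across all 29983 transcripts limma called 0 between AngII and Control. The exact rank sum test also called 0, but its smallest possible p of 0.00433 leaves it little room to pass the adjustment. At an unadjusted p under 0.05 there were 2175 transcripts, 993 higher and 1182 lower in AngII, where chance gives 1499. The libraries of the 2 groups did not overlap in 242 transcripts, 0.807% of those tested, against 0.433% by chance. Without AngII replicate 6, 12 transcripts were called, 9 higher and 3 lower in AngII, MERGE.9452.1 and ENSMUST00000177974 among them, and without any other single library 0 to 3 were called. With AngII replicates 2 and 6 and neferine replicate 1 left out there were 6, of which 5 were higher and 1 lower. A limma fit of only these 2 groups called 7, of which 2 were higher and 5 lower. MERGE.36888.4 and MERGE.36888.5 were among the 7, with adjusted p of 0.000705 and 2.69e-05 in that fit (0.000502 to 0.536 and 1.73e-08 to 0.536 over all alternatives). Almost all of their spread in that fit comes from 1 group, which helps to lower these p. The SD was 0 for MERGE.36888.4 in Control and 0.00789 for MERGE.36888.5 in AngII. The fit of all groups holds these low SDs too, and also the spread of the neferine libraries. In neferine replicate 3, MERGE.36888.4 was listed at 0 and MERGE.36888.5 was at 24.9, and both transcripts passed without that library. The upper ends of 0.536 come from the exact rank sum test.

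AngII with neferine was compared with AngII to find transcripts that differ when neferine is added to the infusion. MERGE.9452.1 had a value of 7.07 ± 1.92 (SD, n = 6) with neferine against 18 ± 5.29 (SD, n = 6) without, a log2 fold change of -1.23 ± 0.209 (SE) that did not pass (limma, adjusted p = 0.306). It passed with library weights (adjusted p = 0.042, against 0.042 to 0.821 over all alternatives). ENSMUST00000030154 was listed at 0 in 5 of the 6 AngII libraries and at 1.05 in replicate 1. With neferine it was listed at 0 in replicate 5 and lay between 3.55 and 6.57 in the others (limma, adjusted p = 0.331), while the Control libraries lay between 4.08 and 5.46. It passed when neferine replicate 5 was left out (limma, adjusted p = 0.000398, against 0.000398 to 0.91 over all alternatives). MERGE.50557.3 was at most 0.0113 in AngII and between 1.20 and 7.79 with neferine (limma, adjusted p = 0.331). In Control it was at most 0.00561 in replicates 1, 2 and 5, and at 2.84 and 1.85 in replicates 4 and 6. MERGE.9086.7 lay between 9.27 and 40.2 in AngII and was listed at 0 in all 6 neferine libraries (limma, adjusted p = 0.306), as it was in 2 of the 5 Control libraries. It passed in a limma fit of only these 2 groups (adjusted p = 0.00135, against 0.00135 to 0.821 over all alternatives). The neferine values, all listed at 0, add no spread in that fit or in the fit of all groups, which helps to lower both p. The fit of only these 2 groups also leaves out the spread of Control. There MERGE.9086.7 was listed at 0 in replicates 4 and 6 and lay between 10.9 and 18.6 in the others. The upper ends of 0.821 and 0.91 over all alternatives come from the exact rank sum test.

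Limma called 0 of the 29983 transcripts between neferine and AngII. The exact rank sum test called 0, with the same limit at a smallest possible p of 0.00216. At an unadjusted p under 0.05 there were 1564, 871 higher and 693 lower with neferine, where chance gives 1499. The groups did not overlap in 79 transcripts, 0.263% against 0.216% by chance. Without AngII replicate 6 limma called 11 transcripts, 1 higher and 10 lower with neferine. Without that library, AngII replicate 2 and neferine replicate 1 it called 15, of which 4 were higher and 11 lower, and a fit of only these 2 groups called 2, both lower. The neferine files are a separate set, so the treatment and the file set cannot be told apart here.

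**Figure D3:**
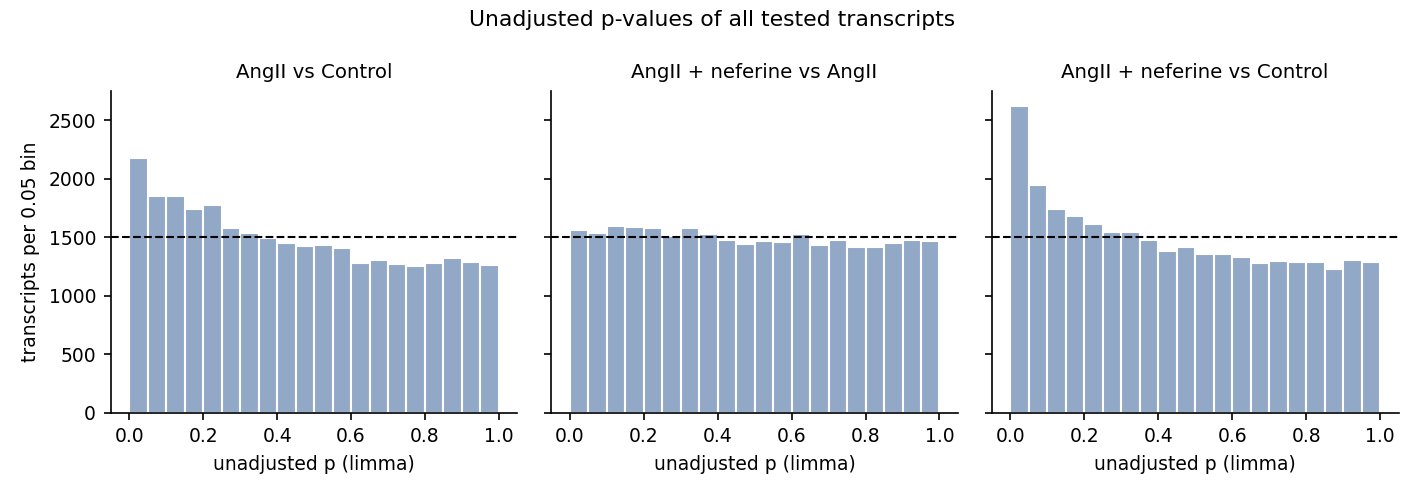
Unadjusted limma p-values of 29983 transcripts in bins of 0.05, with the number of transcripts on the vertical axis and the number expected by chance, 1499, as a dashed line. The lowest bin holds 2175 transcripts for AngII against Control, 1564 for neferine against AngII and 2622 for neferine against Control.

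A further comparison asked whether transcripts moved one way by AngII moved back with neferine. No transcript was called in both comparisons with opposite signs (limma, 0 of 29983). At an unadjusted p under 0.05 in both, 314 had opposite signs, 143 of them higher in AngII and then lower with neferine and 171 the reverse. Opposite signs are frequent by construction because both comparisons use the AngII libraries, and 20 simulated datasets with unchanged groups gave 313.1 on average. Independent lists would give 22.95 and 34.34. A further 23 had the same sign. Among the transcripts named above, MERGE.9452.1 and ENSMUST00000030154 had neferine values for which no difference from Control was detected, with unadjusted limma p of 0.228 and 0.297. The rows of the files favor such a return for transcripts low in AngII, such as ENSMUST00000030154, MERGE.50557.3 and MERGE.36888.5. All 502 tested transcripts with an AngII mean under 0.5 have means above 0.5 in Control and with neferine, since the files list no others. They make up 40 of the 171 and 114 of the 871 higher with neferine than in AngII.

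The covariance of the 2 sets of log2 fold changes across transcripts was -0.0970, against -0.0936 in the simulations, and their correlation was -0.393 against -0.476. Transcripts are not independent replicates. With the AngII libraries split 3 and 3, so that the comparisons shared none of them, the covariance was 0.0219 on average over 20 splits (SD 0.0166 between splits) and 0.000401 in the simulations. A return toward Control would make it negative. Without AngII replicates 2 and 6 and neferine replicate 1 it was -0.00333, and 5 transcripts were called in both comparisons with opposite signs. Without AngII replicate 6 alone 7 were called.

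AngII with neferine was compared with Control to find transcripts that still differ from saline when neferine is given. Only transcripts listed in both sets of files could be tested. A further 4138 were listed only with Control and AngII, 393 of them with an AngII mean of at least 0.5. The others had a mean of at least 0.5 in Control and under 0.5 in AngII. Transcripts under 0.5 both in AngII and with neferine are therefore missing here, which leaves out falls to that level in both. Of the 29983 transcripts 11 passed, all from Ensembl, with 10 higher and 1 lower with neferine. This balance differed in other fits, with 14 higher and 12 lower when only these 2 groups were fitted and 74 and 32 without AngII replicates 2 and 6 and neferine replicate 1. The exact rank sum test, with a smallest possible p of 0.00433, called 0. ENSMUST00000112747 rose most on the log2 scale, by 5.20 ± 0.694 (SE; limma, adjusted p = 0.0245). It was at most 0.805 in Control, between 0.364 and 7.64 in AngII and between 11.7 and 463 with neferine. ENSMUST00000113237 rose by 2.46 ± 0.407 (SE; limma, adjusted p = 0.0483), from at most 0.526 in Control, where 2 libraries were listed at 0, to 5.86 ± 2.70 (SD, n = 6) with neferine, with 3.92 ± 3.83 (SD, n = 6) in AngII. ENSMUST00000174734 fell (limma, adjusted p = 0.0245): it lay between 2.99 and 7.10 in Control, was at most 3.11 in AngII with 1 library listed at 0, and was listed at 0 in all 6 neferine libraries. Over all alternatives the adjusted p of these transcripts lay between 0.000789 and 0.208, between 0.00595 and 0.208, and between 0.000826 and 0.208. The call was lost in 7 of 28, 17 of 27 and 8 of 27 settings. The upper ends come from the exact rank sum test, which has little room to pass and is among the settings that lost each call. The losses of ENSMUST00000113237 include the fits without a filter (adjusted p = 0.0643) and without trend (adjusted p = 0.0512). The absolute log2 fold changes of the 11 lay between 1.27 and 5.20.

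All 11 transcripts differed from Control in the same direction in AngII, 10 of them at an unadjusted p under 0.05. The Control libraries that the comparisons have in common give much of this by themselves. In 20 simulated datasets with unchanged groups, 10.8 of the 11 transcripts with the smallest p had the same direction on average. On average 7.5 also had an unadjusted p under 0.05 (limma), with a range of 5 to 9. For rises from a low Control mean the rows of the files add to the agreement, which the simulations do not reproduce. A transcript with a Control mean under 0.5 is listed only with an AngII mean of at least 0.5. ENSMUST00000112747 and ENSMUST00000113237, with Control means of 0.187 and 0.193, are such transcripts. The rows work against agreement for falls to a neferine mean under 0.5, as in ENSMUST00000174734. Such a transcript is also listed only with an AngII mean of at least 0.5. With the rows acting in both ways, the observed 10 against 5 to 9 can not be read as an excess. All 11 also had the same direction between neferine and AngII, 7 of them at an unadjusted p under 0.05, about what the shared neferine libraries give in the same simulations, 10.2 and 5.85 of 11, with ranges of 8 to 11 and 3 to 9. Across the 29983 transcripts, the differences of AngII and of neferine from Control had a covariance of 0.176, against 0.113 in simulations with unchanged groups, and a correlation of 0.612 against 0.545. With the Control libraries split 2 and 3, the covariance was 0.0583 over 10 splits, against -0.000389 in the simulations. The simulated transcripts vary independently of each other, unlike those of real libraries. The simulations therefore do not show how far such a covariance strays by chance.

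At an unadjusted p under 0.05 there were 2622 transcripts between neferine and Control, 1267 higher and 1355 lower, where chance gives 1499. The groups did not overlap in 625 transcripts, 2.08% against 0.433% by chance. The calls depended on single libraries: limma called 0 without Control replicate 2, 4 or 5 or neferine replicate 2, and 31 without AngII replicate 6, 24 higher and 7 lower, among them all 11. Without AngII replicates 2 and 6 and neferine replicate 1 it called 106, among them all 11. As for the comparison with AngII, the treatment and the file set cannot be told apart.

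**Figure D4:**
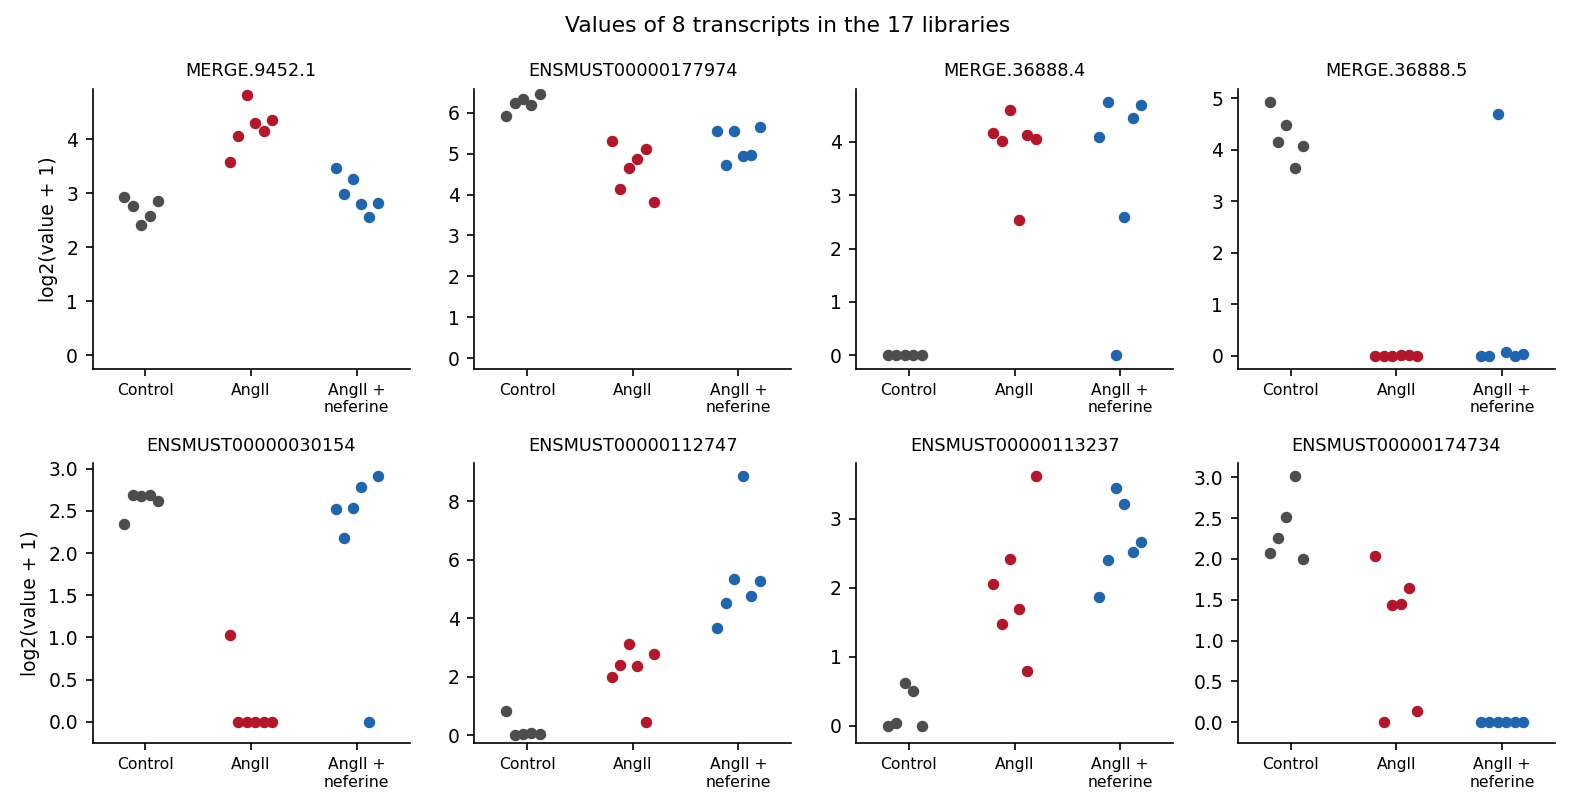
Values of 8 transcripts as log2(value + 1) on the vertical axis, with 1 point per library and the groups on the horizontal axis. MERGE.36888.4 and MERGE.36888.5 take each other's place between Control and AngII, ENSMUST00000030154 is listed at 0 in 5 AngII libraries, and ENSMUST00000112747 lies above the Control range in all 6 neferine libraries.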

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

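Apart from the test of the file sets on held-out Control libraries, the tests in this part were chosen after the results were seen. Of 48 groups of 5 or 6 values examined, 12 had 1 library far from the others. Chance gives about 5%, and several of the 12 concern the same transcripts or libraries.

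AngII replicate 6 was far from the other AngII libraries in its median Spearman rho, 0.455, and in the share of transcripts listed at 0, 16.4%. In 136 transcripts its value was at least 5 and at least 10 times that of any other library, against 9 to 18 such transcripts in the other AngII libraries; these held 0.438% of its signal. A lower depth was not borne out, since its relative depth of 1.02 lay within the range of the other libraries, and neither was a loss of signal to a few transcripts, since its 10 highest transcripts took 14.9%. RNA of another tissue may be a candidate source of the 136 transcripts, but no tissue can be tested without gene names, and RNA quality or a biological difference of this sample stayed open and untested.

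The exchange between MERGE.36888.4 and MERGE.36888.5 was complete between Control and AngII, and neferine replicate 3 showed the Control state, with MERGE.36888.5 at 24.9 where the other neferine libraries were at most 0.0499. AngII replicate 4 had the lowest MERGE.36888.4 value of its group, 4.78. The summed locus changed by -0.33 (log2) between AngII and Control. Its 95% interval of -1.14 to 0.478 rests on a normal approximation and is slightly narrow for so few samples. A total that is kept while reads go to one or the other isoform could give these values, and so could a true change of isoform. Among 9093 pairs of assembled transcripts of 1 locus, 4 had exactly 1 member at 1 or more in each library and the other under 0.5, and this pair alone parted Control from AngII. Of the 462 arrangements of the 11 libraries, 3 parted as many pairs. This decides nothing, because 4 pairs are too few for any larger share and this kind of pair was defined only after the pair had been seen, so a random assignment that follows the groups by chance stays open.

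For the 11 transcripts called between neferine and Control, a difference between the file sets may be the cause. In each of 10 splits of the Control libraries, 11 transcripts were chosen between neferine and 3 Control libraries, and their direction was read between AngII and the other 2, which belong to 1 file set. On average 7.1 of 11 had the same sign, with a range of 5 to 8. A file set alone would leave same and opposite signs about equally frequent only if the listed rows favored neither. For rises from a Control mean under 0.5 they favor the same sign, since such a transcript is listed only with an AngII mean of at least 0.5. For falls to a neferine mean under 0.5 they work against it, since these too are listed only with an AngII mean of at least 0.5. The number to be met by a file set alone is therefore not known. This test neither excludes the file set as the whole cause nor bears it out. Neferine and the file set cannot be told apart for these transcripts, since all neferine files belong to the separate set.

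The other values far from their group were these. Neferine replicate 1 had the highest total signal, 569873. Control replicate 5 and AngII replicate 2 had the highest shares of signal in the 10 highest transcripts of their groups, 21.8% and 31.0%. ENSMUST00000030154 was at 4.08 in Control replicate 1, at 1.05 in AngII replicate 1 and at 0 in neferine replicate 5. ENSMUST00000112747 was at 0.805 in Control replicate 1 and at 463 in neferine replicate 4.

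The 2028 transcripts listed only in the neferine files entered no comparison. Of these, 1 had a value of at least 1 in all 6 libraries. The highest mean among them was 101, for a transcript listed at 0 in replicates 1 and 2 and between 128 and 174 in the others.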

How the results depend on the processing

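Leaving out AngII replicates 2 and 6 and neferine replicate 1 together, library weights, Ensembl transcripts alone, all rows of the Control and AngII files and locus sums were chosen after seeing the data, as were the covariances. The cause of the differences was not tested. For AngII against Control, neferine against AngII and neferine against Control the counts were 0, 0 and 11. A fit of only the groups compared gave 7, 2 and 26, library weights 6, 3 and 63, and leaving out the 3 libraries 6, 15 and 106, which held all 11. For neferine against Control the count was 17 with quantile normalization (all 11 among them), 4 without a filter, 6 without trend and 17 with Ensembl transcripts alone. It was 0 with the exact rank sum test, whose p cannot go below 0.00433. For AngII against Control the count was 1 with a minimum of 5 in 5 libraries, 1 of 5368 locus sums, and 7 with all rows in a fit of only those groups, as with shared rows. Calls with opposite signs were 0, 5 without the 3 libraries and 2 with weights.

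Without 1 library there were 0 to 12 calls for AngII against Control, 0 to 11 for neferine against AngII, 0 to 31 for neferine against Control and 0 to 7 with opposite signs, the highest without AngII replicate 6 in each case. For AngII against Control there were 2 calls without AngII 1 or neferine 3, 3 without neferine 5, and 1 without neferine 2, 4 or 6. For neferine against AngII there was 1 without neferine 2 or 5, and as many with opposite signs. For neferine against Control there were 0 without Control 2, 4 or 5 or neferine 2, 1 without neferine 4 or 6, 3 without AngII 4, 5 without Control 1, AngII 1 or neferine 3, 6 without Control 6 or AngII 3, and 27 without neferine 1. The split covariance of the AngII and neferine effects, 0.0219, lay between 0.0119 and 0.0324. It was 0.0537 with a pseudocount of 0.1 and reversed to -0.00333 without the 3 libraries. That against Control, 0.0583, lay between 0.0461 and 0.0686, and was 0.0444 without a filter, 0.0968 with the minimum of 5 and 0.1315 with the pseudocount.

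Replicate numbers did not pair the samples: deviations of same-numbered samples correlated between -0.147 and 0.064 in 16 pairs, and 2 were best with their own number. With the number as a block, neferine against Control had 0 calls and the others stayed at 0.

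The 10 named transcripts kept their direction in all 303 values under alternatives. This was largely fixed in advance, because the transcripts were picked from these same data. Their groups did not overlap in the comparison they were named for, apart from ENSMUST00000030154 between neferine and AngII. Of the 303 values, 255 stayed on their side of the threshold, 32 no longer passed and 16 came to pass. ENSMUST00000113237 lost its call in 13 of 17 fits without 1 library, ENSMUST00000174734 in 6 and ENSMUST00000112747 in 5; Control 2, 4 and 5 and neferine 2 and 6 ended all 3. MERGE.9452.1 passed between AngII and Control without AngII 1, AngII 6 or neferine 5, ENSMUST00000177974 without AngII 6, MERGE.36888.4 and MERGE.36888.5 without neferine 3, and ENSMUST00000030154 between neferine and AngII without neferine 5. Protein-coding genes alone, a composition covariate and the gene list alternatives were not run for want of gene names. The limit set by depth is unknown.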

Other observations

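The tests in this part were chosen after the counts of the comparisons had been seen. For each comparison the same libraries were split at random into groups of the same sizes, 100 splits with the real one included. The rows of the files depend on the means of the real groups, so the real split is not on an equal footing with the others. How much this changes the counts was not tested. The chance figures given for the comparisons above take no account of it either. For neferine against Control only the real split, 1 of 100, gave as many as 11 calls, with at most 5 in another. It was also the only one, 1 of 100, with as many as 2622 transcripts at an unadjusted p under 0.05, with at most 1872 in another. A share of 1 of 100 is the smallest these splits can reach, and it holds no allowance for the other counts tested. Such counts were therefore rare among the splits, but chance was not firmly excluded. For AngII against Control, 4 of 100 splits gave as many as 2175 transcripts at an unadjusted p under 0.05. This share lies under 5% with no allowance for the other counts tested, and 3 splits gave more than the real one, up to 2788, so chance was not firmly excluded. For neferine against AngII chance was not excluded: 31 of 100 splits gave as many as 1564 transcripts at an unadjusted p under 0.05, with up to 3151 in another. The 3 splits with the most transcripts put AngII replicates 2 and 6 and neferine replicate 1 on the same side, which points to a structure of the samples other than the groups. Where the real count of calls was 0, as for AngII against Control, for neferine against AngII and for opposite signs, 100 of 100 splits reach it by construction, which says nothing about chance. The highest counts of the other splits were 11, 7 and 2.

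Between Control and AngII, the covariance of the log2 differences from parts of both groups that share no library was 0.0364 across transcripts, against -0.00079 in simulations with unchanged groups. It was 0.0235 without Control replicate 5 and 0.0554 without AngII replicate 1, the lowest and the highest value with 1 library left out. It is an estimate of the variance of the AngII differences that sampling noise does not raise on average. The corresponding covariance of the AngII and neferine differences from Control was 0.0583. The value of 0.0364 holds no neferine library and rises with any difference between AngII and Control, whichever group moved. The value of 0.0583 measures a difference from Control that AngII and neferine have in common. Both use the Control and AngII libraries and are not separate results. The simulated transcripts vary independently of each other, so the simulations do not show how far either value strays by chance. Whether the differences from Control come from the infusion or from the handling of the Control samples was not tested.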
